A study of Mus musculus with 8 samples.

How the data were processed

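RNA of macrophages taken from the peritoneal cavity of mice after thioglycollate broth, an irritant that draws leukocytes into the cavity, was sequenced in 8 libraries. Sample titles carry the letter M or F, the genotype WT or KO and an animal number. The letters are not spelled out in the labels and are kept here as written. Groups were taken from the titles and the genotype labels, which gave 3 M_WT, 3 M_KO, 1 F_WT and 1 F_KO libraries. The titles give each library its own animal number, and the labels say nothing more of litters, cages or days. The numbers differ between the groups, so no pairing was used.

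Per the labels' protocols, libraries were made with a NEBNext Ultra RNA kit. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.16.1, with the builds GRCm38 and mm10. How multi-mapping reads were treated, the strand setting and the annotation release are not given in the sources used here. The deposited count table holds whole read counts per gene that the authors did not normalize, for 54532 gene rows, of which 28170 had no count in any library. The deposited FPKM table holds FPKM values, fragment counts scaled to gene length and library size. FPKM times gene length over count was 1 constant per library, between 0.891 and 1.08 of the value that the library's total count gives. In the authors' deposited comparison of M_KO with M_WT, the per-library values are a signal made by the authors from the counts. Their ratio to the counts varied within a library, from 0.774 to 0.834 in M_KO_5642 over genes with at least 20 counts. The same deposited table gives log2 fold changes and p-values for 23513 rows, and its adjusted p-values equal the Benjamini-Hochberg adjustment of its p-values over those rows. No deposited value column was without a sample or group (0 columns), and 8 columns that a second deposited table repeats for the called genes were not used.

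Total counts ran from 18206427 to 22853583 per library. A count of 0 allows up to 3 counts, which is 0.120 to 0.170 TMM-scaled CPM depending on the library. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

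Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with TMM scaling, after edgeR's default expression filter on genotype. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The M comparison used the 6 M libraries (13646 genes, 4 residual degrees of freedom, biological coefficient of variation 0.30). Models over all 8 libraries (13751 genes) had genotype and letter as terms, or their interaction. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. CPM values are scaled by TMM over all 8 libraries. F_KO and F_WT have 1 library each and were compared without a test, as differences of log2 CPM with a prior count of 2. Gene lists fixed beforehand (33 lists, of which 32 had at least 2 measured genes) were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM, beside camera with an estimated correlation and fry. In the F pair, the median of a list was placed among 10000 random lists matched on mean expression in 20 bins.

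The groups, main tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule names Men1, then up to 8 rising and 8 falling protein-coding genes with the largest fold change among those with adjusted p under 0.05, a mean log2 CPM of at least 1, a formal symbol and no overlap of the 3 against 3 libraries, and up to 4 members per list. With edgeR this rule gave 1 gene. After that count was seen, the same rule was also applied to the calls of DESeq2 1.42.0, which had been planned as an alternative, and those genes are named as DESeq2 calls.

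The tests were tried on simulated counts for 13646 genes with the means, library sizes and spread of the real libraries and 200 genes changed by 2-fold or 4-fold. For the M comparison, edgeR recovered 9% of the 2-fold and 60% of the 4-fold changes, with 7 false calls among 76. DESeq2 recovered 39% and 76%, with 56 false calls among 171. For genotype over all 8 libraries edgeR recovered 26% and 77%, and for F against M 14% and 65%. For the interaction it recovered 0% and 1%. In the set test, a list of 30 genes shifted by log2 0.6 was called and 0 of 40 unshifted lists were. The simulated genes varied independently, so this does not give the rate of false calls for lists whose genes vary together. The estimated correlation of the cell cycle list, for example, was 0.92.

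Alternatives were DESeq2, RLE and upper-quartile scaling, no filter or a stricter filter on low counts (at least 1 CPM in at least 3 libraries), limma voom, robust and legacy dispersion estimates, a log2 fold change threshold of 1, fits over all 8 libraries, a covariate for animal numbers beginning with 56, limma on log2(FPKM + 1), a prior count of 0.5, and leaving out libraries.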

Results

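Gene expression was compared between wild-type macrophages and macrophages with a knockout of Men1, which encodes menin, a scaffold protein of histone H3K4 methyltransferase complexes. The cells came from the mouse peritoneal cavity after thioglycollate broth. There were 3 M_WT libraries (M_WT_5643, M_WT_6258 and M_WT_6255), 3 M_KO libraries (M_KO_5944, M_KO_5645 and M_KO_5642), 1 F_WT library (F_WT_5638) and 1 F_KO library (F_KO_5639). Total counts were 21869905, 19163344 and 19864103 in M_WT, 18206427, 19286904 and 22853583 in M_KO, 21883619 in F_WT and 21474093 in F_KO, in that order of libraries. Libraries of a group had Spearman correlations across genes between 0.959 and 0.988, and no such pair agreed within sampling noise. Over all pairs the range was 0.949 to 0.988, so libraries of different groups could be as close. M_WT_6258 and M_WT_6255 were the closest pair (0.988), but M_WT_5643 was closer to M_KO_5944 (0.984) than to either (0.973 and 0.976).

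Men1 (ENSMUSG00000024947, chromosome 19, 6334979 to 6340891, plus strand, GRCm38) was lower in every KO library than in every WT library. It was at 25.7, 17.1 and 21.4 CPM in M_WT and at 8.15, 6.45 and 8.42 CPM in M_KO. The means were 21.4 ± 4.30 and 7.68 ± 1.07 CPM (SD, n = 3 each), so that M_KO held 35.8% of the M_WT level. The log2 fold change was -1.49 (SE 0.21), with an edgeR adjusted p of 0.284, which did not pass the threshold, and a DESeq2 adjusted p of 4.49e-06. An exact two-sided permutation test of the 3 against 3 libraries gave p = 0.1, the smallest p this design allows. In the F pair, Men1 was at 18.1 CPM in F_WT and 11.7 CPM in F_KO, a ratio of 0.645 (95% exact Clopper-Pearson interval 0.549 to 0.758, counting error only). Transcript therefore remained in every KO library, and the counts do not show which exons it came from.

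EdgeR called Lif and 2 other genes in M_KO against M_WT. Lif, a cytokine of the interleukin-6 family (ENSMUSG00000034394, chromosome 11, 4257557 to 4272514), fell from 38.1 ± 4.06 to 8.32 ± 1.67 CPM (SD, n = 3 each; log2 fold change -2.20, SE 0.19, edgeR adjusted p = 0.0476). The other 2 calls rose: Rps2-ps10, a ribosomal protein pseudogene on chromosome 18 (61259008 to 61259972), and Gm11361 on chromosome 13 (28257528 to 28258134). Rps2-ps10 went from 15.1 ± 3.29 to 228.1 ± 22.6 CPM (log2 fold change 3.91, SE 0.21) and Gm11361 from 7.34 ± 0.64 to 111.1 ± 26.4 CPM (log2 fold change 3.91, SE 0.22), each with an edgeR adjusted p of 0.00373. These 2 genes fall outside the rule for named genes and were chosen after their values were seen. Both are near-identical copies of ribosomal protein genes, so their counts are uncertain. In all, edgeR called 3 of 13646 genes, with 1304 at an unadjusted p under 0.05, and 2189 genes (16.0%) had M_KO and M_WT libraries that did not overlap, where chance gives 10%. The count was 0 without M_WT_6255, 5 without M_WT_6258, 5 without M_KO_5944 and 21 without M_WT_5643, and the Lif call was lost without any 1 library other than M_WT_5643 (adjusted p from 0.062 to 0.320).

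**Figure D1:**
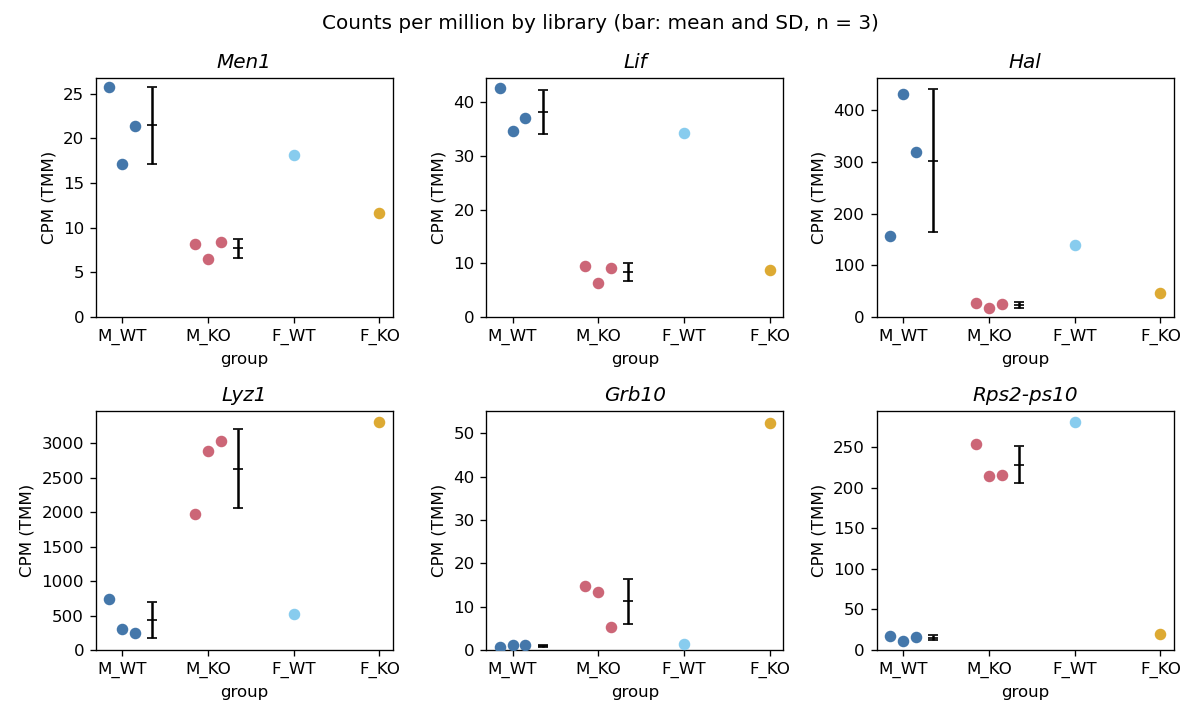
CPM (TMM-scaled, linear axes from 0) of 6 genes in each library, grouped by letter and genotype; points are single libraries, and bars give the mean and SD of the groups with n = 3. Lif lies near 34.2 CPM in F_WT and 8.83 CPM in F_KO, close to the M groups, while Rps2-ps10 is at 280.3 CPM in F_WT and 19.8 CPM in F_KO, opposite to the M groups.

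DESeq2 called 187 genes in the same libraries, 94 rising and 93 falling, and the authors' deposited table calls 130, 64 rising and 66 falling. Of the 187 genes, 112 are also called in the authors' deposited table, as are the 3 edgeR calls. Among DESeq2 calls with the largest rise were Grb10, an imprinted adaptor of growth factor receptors (0.97 ± 0.25 to 11.2 ± 5.11 CPM, SD, n = 3 each), and Lyz1, which encodes lysozyme (435.6 ± 266.5 to 2631.6 ± 576.0 CPM). Their log2 fold changes were 3.52 (SE 0.48, DESeq2 adjusted p = 5.15e-10) and 2.58 (SE 0.42, DESeq2 adjusted p = 1.0e-06). The others were Tmem132e (3.35), Zfp984 (3.27), Strip2 (3.0), Dbp, a circadian transcription factor (2.78), the MHC class I gene H2-Q1 (2.60) and Thbs2, a matrix glycoprotein (2.49), all as DESeq2 log2 fold changes. Single libraries carried part of these rises. The edgeR log2 fold change of Strip2 went from 3.01 to 1.43 and that of Dbp from 2.78 to 1.57 without M_KO_5645, that of Tmem132e from 3.33 to 2.17 without M_KO_5944 and that of Zfp984 from 3.27 to 2.65 without M_KO_5642, while Lyz1 went from 2.59 to 3.22 without M_WT_5643.

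Among the DESeq2 calls that fell, Hal, encoding histidine ammonia-lyase, went from 302.2 ± 138.2 to 23 ± 5.40 CPM (SD, n = 3 each; log2 fold change -3.73, SE 0.38, DESeq2 adjusted p = 1.72e-18). Csf2, the growth factor GM-CSF, had a log2 fold change of -3.37, Plat, tissue plasminogen activator, -3.18, the collagenase gene Mmp13 -2.89 and the protease gene Htra4 -2.57. Armcx4 was at -2.83, Pcna-ps2 at -3.35 and Gapdh at -2.82. Pcna-ps2 carries a pseudogene symbol, and Gapdh, a glycolytic enzyme with many near-identical copies, was counted at only 6.10 to 90.4 CPM, so both values are uncertain. The fall of Pcna-ps2 rests on M_WT_5643, at 14.03 CPM against 0.75 and 1.37 CPM in M_WT_6258 and M_WT_6255, and its edgeR log2 fold change went from -3.32 to -0.97 without that library. Without M_KO_5944, Csf2 went from -3.37 to -4.08 and Armcx4 from -2.81 to -3.57 (edgeR). For the 16 genes named here from DESeq2, edgeR's adjusted p lay above the threshold, and leaving out 1 library moved the DESeq2 count between 69 (without M_WT_6258) and 566 (without M_KO_5944). The count was 311 without M_WT_5643, 95 without M_WT_6255 and 99 without M_KO_5645. In simulated counts with this design, 56 of 171 DESeq2 calls were false. That share depends on the 200 genes set as changed and on the spread assumed, so it does not estimate how many of the real calls are false.

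Inflammatory genes were lower in M_KO. Of 29 measured inflammatory cytokines and NF-kB targets, 26 had a lower fitted value and 3 a higher one, with a median log2 fold change of -0.88. EdgeR called 0 of them over all genes, 5 fell when adjusted over the list alone, and DESeq2 called 6, all falling. Ccl4 and Ccl3, chemokines of macrophages, went from 218.3 ± 76.7 to 55.2 ± 14 CPM and from 273.3 ± 59.7 to 109.8 ± 26.1 CPM (SD, n = 3 each), with DESeq2 adjusted p of 2.42e-06 and 8.16e-04. Il1rn, the interleukin-1 receptor antagonist, had a log2 fold change of -1.83 (DESeq2 adjusted p = 1.02e-05) and Tnf -0.91 (DESeq2 adjusted p = 0.00649). The list was called by camera (adjusted p = 2.63e-09), with an adjusted p of 0.615 with an estimated correlation. The list mean, relative to the M libraries, was 0.89, 0.53 and 0.15 in M_WT and -0.12, -0.31 and -1.13 in M_KO.

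Interferon-stimulated genes had the lowest median of the lists. Of 36 measured members, 35 had a lower value in M_KO, with a median log2 fold change of -1.28 (camera adjusted p = 1.95e-14). The adjusted p was 0.615 with an estimated correlation, and 0 members were called by edgeR, over all genes or adjusted over the list alone, or by DESeq2. The list mean was 1.42, 0.92 and 0.32 in M_WT, but 0.72 in M_KO_5944 against -1.68 and -1.69 in M_KO_5645 and M_KO_5642, so the groups overlapped.

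The preset-correlation test called 7 further lists, none with an estimated correlation (adjusted p of 0.615 to 0.822), and fry called 0 lists. Dendritic cell markers (9 of 10 members lower, median -0.86), unfolded protein response genes (19 of 25 lower, median -0.17), glycolysis and hypoxia genes (24 of 31 lower, median -0.19), MHC class II and antigen presentation genes (19 of 24 lower, median -0.32), alternative activation genes (16 of 21 lower, median -0.19) and cell cycle genes (37 of 40 lower, median -0.31) were lower. B cell markers were higher (13 of 14, median 0.73). Of the 32 list means, 3 separated WT from KO in all 8 libraries, where chance gives 2.86%: glycolysis and hypoxia genes (lowest WT 0.04, highest KO -0.04), genes known to depend on menin in other cell types (-0.107 and -0.114, not called, camera adjusted p = 0.145) and neutrophil markers. The glycolysis and hypoxia list holds Gapdh, whose counts are uncertain (edgeR log2 fold change -2.80, 77.4 CPM in F_WT and 12.2 CPM in F_KO). The margin of that list is narrow, and its means without Gapdh were not computed. Without M_WT_6258, 3 lists were called in place of 9. The inflammatory and interferon-stimulated lists were called without any 1 of the 6 libraries, but each of the 7 others lost its call without at least 1. The dendritic cell and unfolded protein response lists lost it without M_WT_6258 (camera adjusted p = 0.160 and 0.0938), glycolysis and hypoxia genes without M_WT_6258 (0.0984) or M_KO_5944 (0.0510), and alternative activation genes without M_WT_5643 (0.0607), M_WT_6258 (0.267) or M_KO_5944 (0.147). The B cell list lost it without M_WT_6258 (0.0984), M_WT_6255 (0.186) or M_KO_5645 (0.362, list mean 0.21 in place of 0.66). The MHC class II list lost it without M_WT_5643 (0.0922) or M_KO_5642 (0.363). Its mean was 0.40 in M_KO_5944, as in M_WT_5643, against -0.53 and -0.54 in M_KO_5645 and M_KO_5642. The difference went from -0.45 to -0.75 without M_KO_5944. The list member H2-Eb1 was at 12.3 CPM in M_KO_5645 and 250.2 to 1006.6 CPM elsewhere, which lowers the mean of that library. The fall of cell cycle genes rests on single libraries: M_WT_5643, at -0.74, lay below every M_KO library, and the difference of -0.21 became -0.01 without M_WT_6258 (0.692), 0.01 without M_WT_6255 (0.792), -0.07 without M_KO_5944 (0.480) and -0.17 without M_KO_5645 (0.170), but -0.63 without M_WT_5643 and -0.39 without M_KO_5642. Of the markers of other cell types, the neutrophil list was not called (4 of 5 measured members higher, median 0.54, camera adjusted p = 0.210), but its mean was lower in every WT library (-0.12, -0.43 and -0.49 in M_WT, -0.23 in F_WT) than in every KO library (0.54, 0.10 and 0.40 in M_KO, 1.02 in F_KO). Other such lists crossed genotype: the mast cell and basophil list mean was 1.31 in M_WT_5643 and 1.55 in M_KO_5944 but -2.36 in M_KO_5642, and the list of resident large peritoneal macrophage genes was at -1.25 in M_KO_5642 and between -0.10 and 0.59 in the other M libraries.

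**Figure D2:**
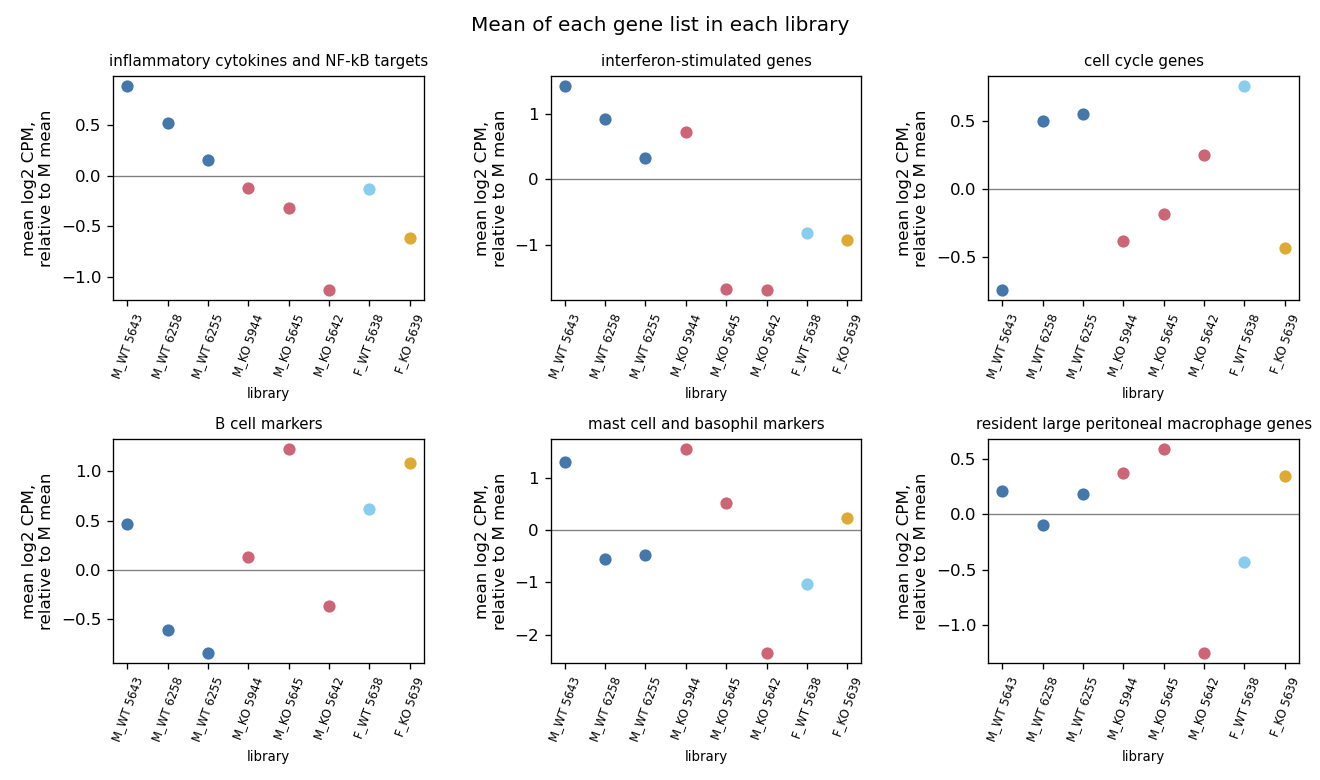
Mean log2 CPM of 6 gene lists in each of the 8 libraries, relative to the mean of the M libraries; each point is a library, coloured by letter and genotype. The inflammatory list lies at or above 0.15 in M_WT and at or below -0.12 in M_KO, while the other 5 lists overlap between M_WT and M_KO; F_WT, at -0.13, lies below M_KO_5944.

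The remaining 23 tested lists were not called. Core macrophage genes had a median log2 fold change of -0.01 over 24 measured members, lysosomal genes -0.06 over 35 and phagocytic and scavenger receptors -0.01 over 36. Within other lists, Vsig4, a complement receptor of resident macrophages, went from 325.4 ± 62.9 to 120.3 ± 28.4 CPM (SD, n = 3 each; DESeq2 adjusted p = 1.77e-05), and Tgfbr2, a TGF-beta receptor, from 79.8 ± 5.66 to 187.0 ± 25.8 CPM (DESeq2 adjusted p = 7.94e-08). Vegfa, a member of the glycolysis and hypoxia list that was called, had a log2 fold change of -1.12 (DESeq2 adjusted p = 4.85e-04).

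The F pair has 1 library per genotype, so its differences have no replicate check. Lif was at 34.2 CPM in F_WT and 8.83 CPM in F_KO (log2 difference -1.92), Hal differed by -1.54, Grb10 by 5.09 and Lyz1 by 2.68, each with the sign of the M comparison. The sign was the other one for Plat (1.69), Armcx4 (1.06), Dbp (-1.15), Zfp984 (-0.97), H2-Q1 (-0.03), Gm11361 (-0.14) and Rps2-ps10 (-3.80), so that of the 3 edgeR calls Lif alone kept its sign. Of the 174 DESeq2 calls that edgeR also tested, 106 (60.9%) had the same sign in the F pair, against 56.2% of all tested genes. The correlation across those 174 genes was 0.24 (Pearson) and 0.21 (Spearman), and genes are not independent replicates. The inflammatory list had a median of -0.22 in the F pair, at the 0.29 percentile of random lists, and the interferon-stimulated list -0.07, at the 17.3 percentile. The inflammatory list does not stand apart by this measure: cell cycle genes lay at the 0 percentile, oxidative phosphorylation genes at 0.03, fatty acid oxidation genes at 0.09 and monocyte genes at 0.18, and B cell markers at 99.99 and resident macrophage genes at 100.

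**Figure D3:**
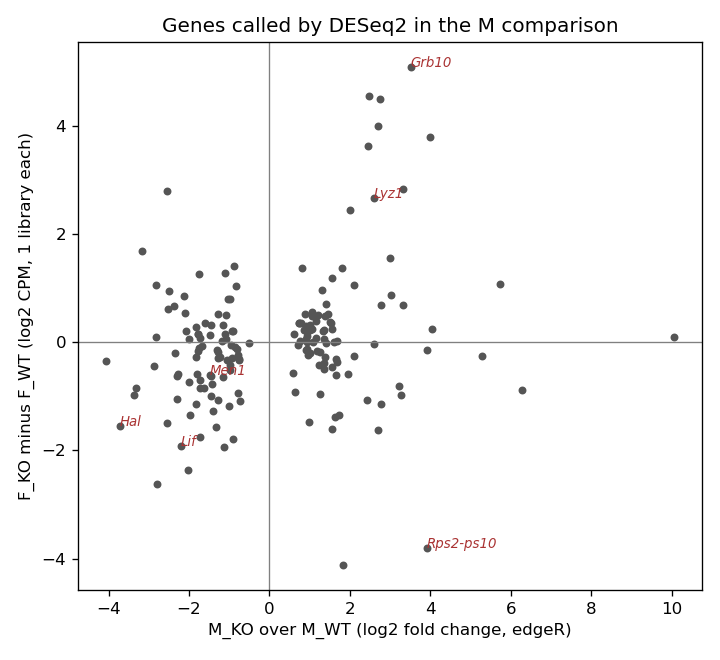
Log2 fold change of M_KO over M_WT (edgeR, horizontal) against the log2 CPM difference between F_KO and F_WT (vertical, 1 library each), for the 174 genes called by DESeq2 in the M comparison; each point is a gene. Of these, 106 lie in the quadrants with matching sign, among them Lif, Hal, Grb10 and Lyz1.

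Over all 8 libraries with the letter as a covariate, edgeR called 1 gene by genotype, Lif (log2 fold change -2.13, SE 0.16, adjusted p = 0.0162), lower in 4 of 4 KO libraries. The count was 0 without M_WT_6258 or M_KO_5944, 2 without M_WT_5643 or F_WT_5638, and 3 without M_KO_5642 or F_KO_5639.

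Between F and M libraries edgeR called 4 genes, all Y-linked and with 0 counts in both F libraries. Ddx3y was at 134.9 ± 6.77 CPM over the 6 M libraries (SD), at least 942-fold higher than the floor of 3 counts in an F library, Eif2s3y at 84.1 ± 5.41 CPM (at least 587-fold), Kdm5d at 23.3 ± 5.90 CPM (at least 162-fold) and Uty at 21.2 ± 3.77 CPM (at least 148-fold). Xist was at 1015.8 and 813.5 CPM in F_WT and F_KO, with 1 count over the 6 M libraries, and was removed by the expression filter. That filter was set on genotype, so genes expressed in the F libraries alone could not be called by this fit. Without F_KO_5639 the count was 9.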

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

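The tests of the explanations for Rps2-ps10 and Gm11361 were chosen after the results were seen, while the interaction test was planned.

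For 3 genes an interaction term between genotype and letter passed the threshold: Rps2-ps10 (log2 -7.72, edgeR adjusted p = 0.0104), Rps3a2 (7.04, adjusted p = 0.0209) and Rps3a3 (6.74, adjusted p = 0.0234). All are members of ribosomal protein families with near-identical copies. Rps3a2 was at 2.74 CPM in F_WT and 208.4 CPM in F_KO, and Rps3a3 at 1.96 and 114.2 CPM. The interaction rests on 1 library per F genotype, with the spread taken from the M libraries, so it has no replicate check in F, and the count of 3 genes was 0 without M_WT_6255 or M_KO_5645, 1 without M_KO_5944 and 6 without M_WT_6258.

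Rps2-ps10 was higher in all M_KO than in all M_WT libraries. In the F pair it was lower in F_KO (280.3 CPM in F_WT, 19.8 CPM in F_KO), so that over all 8 libraries the lowest KO minus the highest WT level was log2 -3.83. With 1 library per F genotype this does not exclude an effect of Men1 loss that is alike in M and F animals. A first rule, on the F difference (log2 -3.80) and the interaction, had counted against that effect and was replaced after its values were seen, since it rested on those 2 libraries. The rule that replaced it could only count for that effect or leave it open. Rps2-ps10 was picked as higher in all M_KO than in all M_WT libraries, so it could not be lower in every KO library. Its parent Rps2, on chromosome 17 (24718116 to 24721929), moved the other way, from 792.3 ± 81.5 to 402.2 ± 31.5 CPM (SD, n = 3 each), and in the F pair from 474.8 to 808.6 CPM. The summed CPM of Rps2 and its copies changed by log2 -0.26, less than the parent. A rising copy added to a falling parent can give such a sum whatever the cause, so this alone does not show shared reads. Reads that pass from parent to copy, for example with a variant of Rps2 carried by some animals, are a candidate explanation. No variant was examined.

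Gm11361 was likewise higher in M_KO, while its parent Rps18 (chromosome 17, 33951999 to 33956001) went from 602.9 ± 78.7 to 205.9 ± 155.7 CPM (SD, n = 3 each), at 26.2 CPM in M_KO_5645 and at 300.9 and 290.5 CPM in M_KO_5944 and M_KO_5642. A first bound, a change of the family sum under log2 1, was met by both families, but the Rps18 sum fell by log2 -0.90, over 0.5 of the parent's change of -1.55. Without M_KO_5645 the changes were -0.61 and -1.03, also over 0.5. A stricter bound was then used, and under it shared reads cannot be told apart from other causes for Gm11361. In the F pair Rps18 was at 323.0 CPM in F_WT and 295.7 CPM in F_KO, below the 553.9 to 693.6 CPM of M_WT. The parent was thus lower in every library where Gm11361 was high, including F_WT. No reads or variants of Rps18 were examined, so this pattern alone does not show shared reads. Gm11361 was at 87.0 CPM in F_WT, a wild type, and at 77.5 CPM in F_KO (lowest KO minus highest WT over all 8 libraries, log2 -0.17), both above the 6.63 to 7.87 CPM of M_WT, with 86.6 to 139.1 CPM in M_KO. So the high level also occurs with Men1 intact, but 1 F_WT library excludes nothing, and the interaction had an adjusted p of 0.0993. As for Rps2-ps10, the comparison over all 8 libraries could not count against an effect of Men1 loss. H2-Ea-ps on chromosome 17 (34342933 to 34344643), near Rps18, was, like Gm11361, low in the M_WT libraries alone.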

How the results depend on the processing

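The legacy estimate, the fits that leave out both M_WT_6258 and M_WT_6255, and DESeq2 without single libraries were chosen after seeing the data; the cause of the shifts below was not tested. EdgeR's 3 genes in M_KO against M_WT (2 rising, 1 falling) became 187 (94 rising, 93 falling) with DESeq2. The count was 16 (9 and 7) with no filter on low counts and 1 (0 rising) over all 8 libraries with the letter as covariate. Without both M_WT_6258 and M_WT_6255, only M_WT_5643 remains in M_WT, so no count is given. The log2 fold change of Lif was then -2.39, against -2.20 with all 6 libraries. The falling count was 0 with upper-quartile scaling, the stricter filter and the covariate for animal numbers beginning with 56. Leaving out 1 library gave 0 to 21 genes, 0 to 10 rising and 0 to 11 falling. The Men1 log2 fold change passed the threshold only with DESeq2 (-1.50). The 9 lists became 0 with an estimated correlation and 0 with fry, and 3 to 10 without 1 library. With the covariate for animal numbers beginning with 56, the MHC class II, B cell and cell cycle lists lost their calls (camera adjusted p = 0.0574, 0.0702 and 0.391). Alternative activation genes lost theirs over all 8 libraries with the letter as covariate (camera adjusted p = 0.0720). Genotype over all 8 libraries gave 132 genes with DESeq2, 7 with no filter and 0 to 3 without 1 library, in place of 1. F against M gave 16 with DESeq2 and 4 to 9 without 1 library, in place of 4. The interaction gave 22 with DESeq2, 1 with limma voom and 0 to 6 without 1 library, in place of 3, and could not be fitted without an F library. No paired analysis was possible because the animal numbers differ between groups.

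The share of genes with the same sign in the F pair was 56.2% with a prior count of 0.5 and 56.3% on log2(FPKM + 1), against 56.2%; no left-out library was run for it. The mean difference of the cell cycle list, log2 -0.21, was -0.01 without M_WT_6258, 0.01 without M_WT_6255 and 0.61 without both, which turned it to higher in M_KO. That of the B cell list turned to lower without both (-0.09). Without both, M_WT_5643 is the only M_WT library, so these values set that 1 library against M_KO and have no replicate check. Its cell cycle mean (-0.74) already lay below every M_KO library, so the turn of that list follows from it. At this depth and with 3 animals per group, 2-fold changes are mostly missed by edgeR: 9% of them were recovered in simulated counts.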

Other observations

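All tests in this part were chosen after the results were seen, except the counts over other splits of the libraries.

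Some genes were on in some animals and nearly silent in others. Chil1, a chitinase-like protein gene, was at 488.8 CPM in M_WT_5643 and 65.6 to 943.2 CPM in M_KO, but at 0 and 0.10 CPM in M_WT_6258 and M_WT_6255. Trim12a was at 50.5 and 50.2 CPM in M_WT_6258 and M_WT_6255 and at or below 0.06 CPM in the other libraries. The MHC class II gene H2-Eb1 was at 12.3 CPM in M_KO_5645 and 250.2 to 1006.6 CPM elsewhere, and H2-Ea-ps had a count of 0 in all M_WT libraries and 2.83 to 11.6 CPM in the others.

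There were 116 genes with a gap of at least 2 on the log2 scale, and 0 (0%) of them split WT from KO in all 8 libraries, which argues against the Men1 genotype as the source of the blocks. Of 21 neighbouring pairs within 1 Mb, 10 (47.6%) shared their split, against a mean of 7.37% and a maximum of 28.6% over 1000 permutations (permutation p = 0.001, the smallest they can give). The pairs that shared their split include neighbours among the Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y, which had 0 counts in both F libraries. Those pairs follow the letter and say nothing of strain, and the share without them was not computed. For the other pairs, strain haplotypes that differ between the animals are a candidate explanation. Neighbours regulated together were not tested as an alternative, and the strain of the animals is not given in the sources used here. The largest class, 23 genes, set M_WT_6258 and M_WT_6255 apart from the other 6 libraries.

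The inflammatory list was lower in all M_KO than in all M_WT libraries. Over all 8 libraries the genotypes overlapped, as the lowest WT mean (F_WT) minus the highest KO mean (M_KO_5944) was log2 -0.00822. Glycolysis and hypoxia genes, genes known to depend on menin and neutrophil markers did separate the genotypes. For the menin-dependent list the margin was as narrow (-0.107 in F_WT, -0.114 in F_KO), so this measure does not set it apart from the inflammatory list. Its median in the F pair was 0.25, with 5 members higher and 4 lower in F_KO. The glycolysis and hypoxia list holds Gapdh, whose counts are uncertain. A first test, the percentile of the F median among random lists (0.29), had counted for Men1 loss and was replaced after its value was seen, since it rested on 1 library per genotype and other lists lay as far out. The comparison over all 8 libraries could not count against Men1 loss, since the list was already lower in all M_KO libraries. The neutrophil list gave no sign of more neutrophils in the M_WT libraries, as its mean was higher in M_KO by log2 0.69, with no overlap of the 3 against 3 libraries. Only 5 of its 15 members were measured, with an estimated correlation of -0.20, so its mean cannot decide whether neutrophil content differed. An effect of Men1 loss and a difference between animals that goes with genotype by chance cannot be told apart with 1 library per F genotype and 3 per M genotype.

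With 10 splits of the 6 M libraries, no share under 0.05 can be had. EdgeR called 3 genes in the real split (1 of the 10 splits reached that count) and at most 0 in another. DESeq2 called 187 genes in the real split (2 of 10 splits reached that count) and 619 in the split of M_WT_5643, M_KO_5944 and M_KO_5645 from the rest, which points to a structure of the samples apart from genotype. Camera called 9 lists in the real split (3 of 10 splits reached that count) and at most 14 in another. Over all 8 libraries, 7 of 35 splits called at least 1 gene, the highest other 144, so chance cannot be excluded for that count. Those splits did not hold the letter fixed, and some put both F libraries in the same part. Splits within each letter were not counted apart.

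Of 203 genes within 5 Mb of Men1, DESeq2 called 2 (0.985%), Men1 itself and Pcna-ps2, against 1.28% elsewhere. Within 5 Mb of Rps18, which takes in the MHC region, it called 6 of 192 (3.13%), against 1.25% elsewhere (Fisher's exact test, two-sided, p = 0.0367), and within 5 Mb of Rps2 2 of 170 (1.18%), against 1.28% (p = 1). The p was 1 around Men1 as well, and these 3 tests were not adjusted. They also take genes as independent, but Rps18, H2-Eb1, H2-Q5 and H2-T23 were all low in M_KO_5645 alone. The windows around Rps18 and Rps2 were centred on parents of genes already called. The 6 calls around Rps18 were H2-Q1, H2-Ea-ps, Tnf, H2-Oa, Ubash3a and Hspa1b. The H2-Q1 rise and the Tnf fall given above thus come from a region where neighbouring genes differed between animals.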
